A study of Mus musculus with 6 samples.

How the data were processed

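The data were gene expression arrays of 6 RNA samples from mouse intestinal organoids, which are cultured mini-tissues grown from epithelial cells. Per the labels, the organoids came from Apc-mutant intestinal adenoma of C57Bl/6 mice and were grown with no added growth factors. They were treated with 300 nM 4-hydroxytamoxifen for 16 h to switch on the CreERT2 recombinase in cells expressing Prox1, and were then sorted by fluorescence. Per the labels, 3 samples held tdTomato-positive (Prox1-positive) cells and 3 held the tdTomato-negative population, which was enriched for Prox1-negative cells. Per the labels' protocols, 50 ng of total RNA was labelled with biotin for an Illumina Expression BeadChip. Nothing in the labels says whether the 3 samples of a group came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical.

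The deposited table of non-normalized values gave a probe intensity on a linear scale for each array. The authors named the table non-normalized, and its array medians differed. It also gave, per the file headers, a detection p-value for each probe on each array. The deposited table of processed values held log2 intensities with equal quantiles on all 6 arrays. These lay within 0.0108 of the quantile-normalized log2 values recomputed from the deposited intensities with no background correction. The software and version that made either deposited table are not given in the sources used here. Every column of per-sample values was matched to a sample by the sample name in the labels.

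From the deposited intensities, background was corrected and arrays were normalized with neqc of limma 3.58.1 in R 4.3.3. This takes the negative-control mean and SD from the detection p-values, adds an offset of 16 and quantile-normalizes. A probe was kept if its detection p was under 0.05 on at least 3 of the 6 arrays, whatever their group. Of 45281 probes, 18299 were kept. The platform annotation gave 1 symbol for 34885 probes, several for 18 and none for 10378. Of the probes with 1 symbol, 34807 had an Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols were changed through it. No coordinates are given, since the files name no genome build. Each gene was represented by its brightest kept probe over all 6 arrays, and probes with no symbol stayed single. This left 12759 rows, called genes below, of which 10133 had a symbol and 2626 had none. Of 3787 genes with several kept probes, 935 had probes of which only some were called and 11 had probes called in opposite directions. Those 11 were Acp2, Cars, Ctns, Dock4, Mtmr11, Pglyrp1, Qrich1, Rps24, Slc9a2, Stab1 and Tpm4. Probes of near-identical genes, such as the Defa family, Lyz1, Gsta1 and Gsta2, can bind each other's transcripts, so which member changed is uncertain.

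The groups were compared with limma (lmFit and eBayes), two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Differences are tdTomato-positive minus tdTomato-negative on the log2 scale, and folds are ratios of normalized intensity, which understate the change of dim probes because of the offset. Errors are SD over 3 arrays or the SE of the limma fit. A probe with a detection p of 0.05 or more on an array has only a bound there. Its fold is then given as "at least", with each such value at the higher of the array's dimmest detected probe and the probe's own value. This setting, chosen after the data were seen, moved list medians by at most 0.12 except for the immune list (0.46 to 0.25) and the neuron and glia list (0.36 to 0.08). The number of arrays limits the precision.

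Before the data were examined, 25 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The rule named Prox1, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, and the 3 members of each list with the smallest unadjusted p. It skipped probes with no symbol and clone or predicted names, and allowed further list members that passed the threshold. Lists with at least 5 measured genes were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 23 lists. Camera compares a list with the other genes. An estimated correlation and fry were alternatives. The members of several lists overlap, with 31 measured genes in more than 1 list.

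Alternatives were 2 other background settings, median centring, the deposited processed values, no filter, a stricter filter, all probes, another variance model, the replicate number as a block, other thresholds and leaving out each array. The same steps were tested on simulated intensities for this comparison, with 14470 rows fitted. They called 1.49% of 67 genes changed by 0.5 log2 units, 55.2% of 67 changed by 1 and 81.8% of 66 changed by 2, with 4 false calls among 96. Only these genes were changed, a far smaller share than the 29.1% called in the real comparison. The adjustment is stricter with so few changed genes, so these rates do not carry over to it. Of 25 simulated lists with no shift, 0 were called with either correlation setting. The simulated genes varied independently, so this result does not test the preset on lists whose genes are correlated. The real S phase and goblet lists had estimated correlations of 0.338 and 0.351. The shifted list was found at an adjusted p of 3.99e-32 with the preset and 0.00928 with the estimated correlation.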

Results

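Expression was measured on 6 arrays, 3 of tdTomato-positive cells, which the labels call Prox1-positive, and 3 of tdTomato-negative cells. Both came from the same kind of Apc-mutant adenoma organoid. Loss of Apc function is known to activate Wnt signalling. Median raw intensity ran from 122.7 to 137.4 over the arrays. Detected probes numbered 18688, 18052 and 18120 in tdTomato-positive replicates 1 to 3, and 17480, 17690 and 17993 in tdTomato-negative replicates 1 to 3. The comparison asked which genes distinguish tdTomato-positive adenoma cells from tdTomato-negative cells, a population only enriched for Prox1-negative cells.

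Prox1, a homeodomain transcription factor and the basis of the sort, was 4.78-fold higher in tdTomato-positive cells. Its log2 intensity was 12.42 ± 0.16 in tdTomato-positive and 10.16 ± 0.96 in tdTomato-negative cells (SD, n = 3 each), a difference of 2.26 (SE 0.42). The limma adjusted p was 0.00793. Each of the 3 tdTomato-positive arrays (12.48, 12.54 and 12.24) lay above each tdTomato-negative array (9.06, 10.70 and 10.73). A second, dimmer Prox1 probe was not detected on tdTomato-negative replicate 1 and was at least 5.61-fold higher in tdTomato-positive cells (limma adjusted p = 0.00114 over all probes). The brighter probe was detected on the tdTomato-negative arrays too, with tdTomato-negative replicate 1 the lowest.

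**Figure D1:**
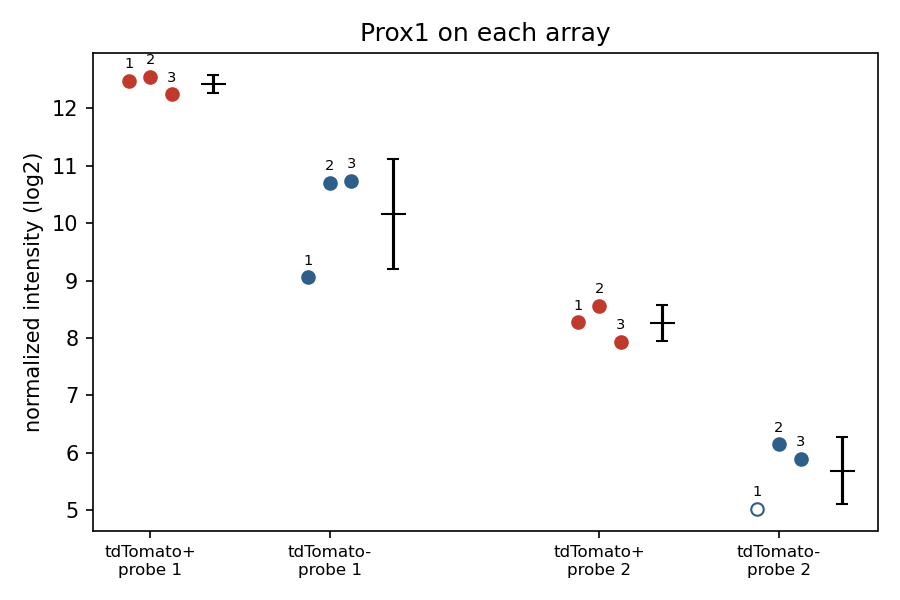
Normalized Prox1 intensity (vertical axis, log2) on each array for both Prox1 probes, with the replicate number above each point and the mean ± SD of 3 arrays as a black bar. The open point is an undetected value, which also enters the mean ± SD beside it. Every tdTomato-positive array lay above every tdTomato-negative array on both probes, and tdTomato-negative replicate 1 was lowest on the brighter probe.

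Among named genes detected on all 6 arrays, Gbx2, a homeobox factor, rose the most in tdTomato-positive cells (difference 4.42, SE 0.21). It was followed by Dkk3 (4.19, SE 0.35) and Bmp4, a secreted growth factor (3.89, SE 0.34). Gbx2 was 21.4-fold, Dkk3 18.3-fold and Bmp4 14.8-fold brighter. Part of the Dkk3 fold came from tdTomato-negative replicate 1, with a log2 intensity of 6.97 against 8.36 and 8.20 on tdTomato-negative replicates 2 and 3. Dlk1, a Notch-related imprinted gene, was detected on 1 tdTomato-negative array and was at least 17.4-fold higher. Spock2, a matrix proteoglycan gene, was not detected on the tdTomato-negative arrays and was at least 15.7-fold higher, and Cntnap4 was likewise at least 9.49-fold higher. Cd177 (14.2-fold), Gulo (14.1-fold), the growth factor Ptn (14.0-fold), the neuropeptide gene Npy (13.5-fold), Atp10a (at least 14.7-fold) and the keratin gene Krt17 (at least 11.6-fold) completed the 12. Part of the Npy fold came from tdTomato-positive replicate 1, with a log2 intensity of 11.52 against 9.38 and 9.32 on replicates 2 and 3. Limma adjusted p for the 12 ran from 2.0e-05 for Atp10a to 0.00477 for Npy.

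Cps1, a urea cycle enzyme, and Dmbt1, a mucosal defence protein, were each detected on 1 tdTomato-positive array. They were at least 26.1-fold and at least 20.6-fold lower in tdTomato-positive cells. Part of both folds came from tdTomato-negative replicate 1. On tdTomato-negative replicates 1 to 3, log2 intensity was 11.91, 9.44 and 9.74 for Cps1 and 11.39, 9.16 and 9.11 for Dmbt1. Enzymes of drug and lipid metabolism were among the largest falls too, with Cyp2c65 16.5-fold, Cyp2s1 15.9-fold, Cyp4f14 14.9-fold, Gsta1 14.2-fold and Gsta2 at least 10.2-fold lower. Sftpd (at least 14.7-fold), the goblet cell lectin Zg16 (at least 11.7-fold), Trim31 (at least 13.7-fold), Tm4sf5 (14.0-fold) and Prap1 (difference -3.70) made up the rest of the 12. Zg16 (10.11, 7.94 and 8.37) and Tm4sf5 (11.48, 9.57 and 9.69) were also brightest on tdTomato-negative replicate 1. Limma adjusted p for these 12 ran from 2.5e-05 for Gsta1 to 0.00323 for Cps1. Probes of Gsta1 and Gsta2 can bind both transcripts, so their values are not independent.

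**Figure D2:**
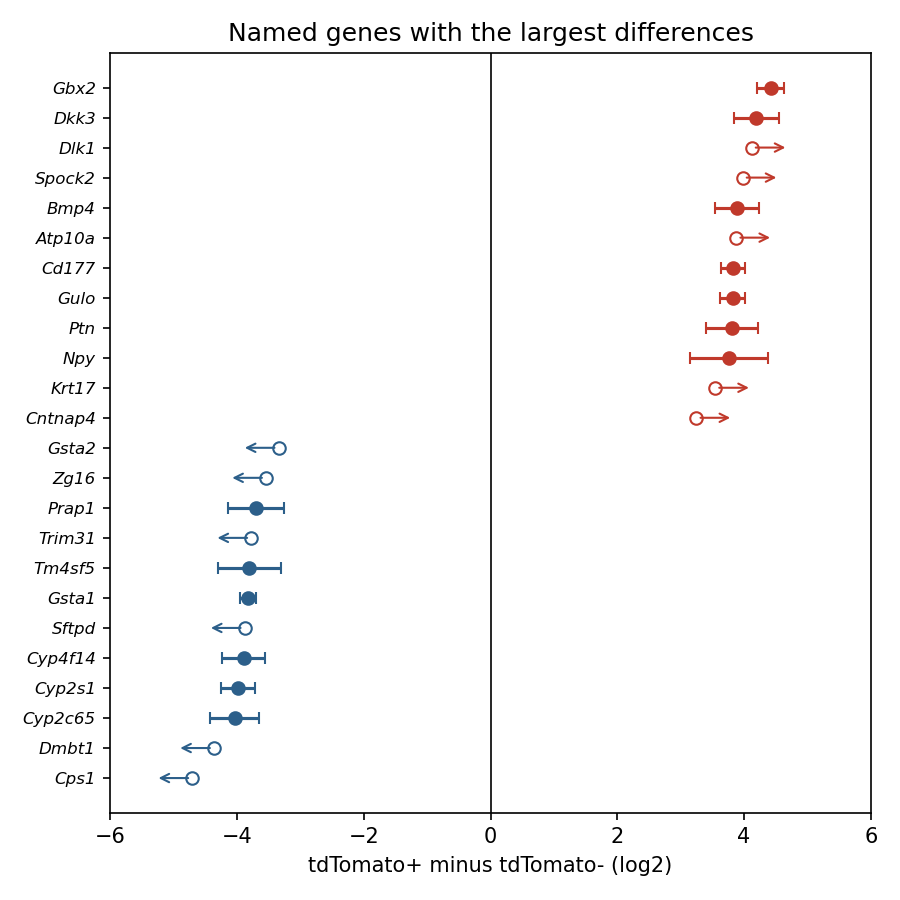
Difference between tdTomato-positive and tdTomato-negative cells (horizontal axis, log2) for the 12 named genes with the largest fitted rise (red) and the 12 with the largest fall (blue), with the SE of the limma fit as bars. Open points with arrows are lower bounds for genes not detected on every array, with undetected values at the dimmest detected probe. Values ran from -4.71 for Cps1, a bound, to 4.42 for Gbx2.

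In all, 3718 of 12759 genes (29.1%) passed the limma threshold, 2003 higher and 1715 lower in tdTomato-positive cells. A fitted change of at least 2-fold was seen for 721 genes that rose and 495 that fell, and one of at least 8-fold for 58 and 24. The groups did not overlap for 6312 genes (49.5%, where chance gives 10%). Of the called genes, 207 were higher with no detection on any tdTomato-negative array and 91 were lower with no detection on any tdTomato-positive array. Of the called genes 53.9% were higher, against 66.3% with each array centred on its median in place of quantile normalization, a scaling that moved the median of all genes by 0.10 log2 units. The count fell to 2137 without tdTomato-positive replicate 1 and to 1926 without tdTomato-positive replicate 2.

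The first principal component (75.7% of the variance) separated the groups, and tdTomato-negative replicate 1 stood apart from its group. Its correlation across genes was 0.980 with tdTomato-negative replicate 2 and 0.979 with replicate 3, which correlated at 0.994 with each other; genes are not independent replicates. Without it, 3933 genes passed, 2076 higher and 1857 lower, and Prox1 differed by 1.70 (limma adjusted p = 0.000587).

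Markers of enterocytes, goblet cells and Paneth cells were lower on balance in tdTomato-positive cells. Of 17 measured enterocyte genes, 10 fell, 1 rose and 6 did not pass (median -0.92). Krt20, a keratin of mature cells, was at least 7.44-fold lower, the lipoprotein gene Apob 4.70-fold and the microvillus gene Vil1 2.03-fold, whereas the peptidase gene Anpep rose by 0.92. Of 16 goblet genes, 9 fell, 2 rose and 5 did not pass (median -1.32). Ccl9 was 7.22-fold, Guca2a 4.42-fold, Spink4 4.01-fold and the mucin gene Muc2 4.61-fold lower, and Bcas1 and Foxa3 rose. Of 15 Paneth genes, 9 fell, 1 rose and 5 did not pass (median -0.89). The defensin gene Defa23 was 3.55-fold and Ang4 2.46-fold lower, with the member of the Defa family uncertain, while Pnliprp2, a pancreatic-type lipase, was 4.00-fold higher.

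Adjusted over the list alone, 12 enterocyte genes fell and 1 rose, 10 goblet genes fell and 3 rose, and 10 Paneth genes fell and 1 rose. Camera of limma called all 3 lists lower, with adjusted p = 5.03e-05 for enterocyte, 0.00715 for goblet and 0.00118 for Paneth genes. With an estimated correlation the adjusted p was 0.35, 0.579 and 0.483. The strict filter, a detection p under 0.01 on all 6 arrays, ended the enterocyte and goblet calls (adjusted p = 0.160 and 0.0660), and of the 8 enterocyte genes it left 3 fell and 1 rose. This filter removes genes that fell out of detection in tdTomato-positive cells, such as Krt20 and Zg16, each detected on 1 tdTomato-positive array. The genes left had medians of -0.78 for enterocyte and -1.28 for goblet. The lost calls are thus not evidence against the falls of the genes removed. Without tdTomato-positive replicate 2, 5 Paneth genes fell, 8 goblet genes fell and 1 rose, and the 1 enterocyte rise was lost without tdTomato-positive replicate 2 or 3.

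Genes shared by most intestinal epithelial cells were divided. Of 14 measured, 6 fell, including Lgals4 (2.49-fold), Krt19 (2.86-fold), Cldn7 (1.83-fold) and the transcription factor gene Hnf4a (1.69-fold), and 8 did not pass. The count adjusted over the list alone was also 6, and 4 fell without tdTomato-positive replicate 1 or 2. The list was called lower with a median of -0.17 (camera adjusted p = 0.0260; adjusted p = 0.35 with an estimated correlation and 0.0660 with the strict filter). Krt8, Krt18 and Cdh1 differed by -0.03, 0.18 and -0.12.

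Fetal-like and regenerative epithelium genes fell on balance. Of 15 measured, 8 fell, 4 rose and 3 did not pass (median -0.90). Il1rn was 7.87-fold, the annexin gene Anxa3 5.85-fold and Msln 3.44-fold lower, whereas Il33, Ankrd1, Ccn1 and Cldn4 rose by 1.52, 1.10, 0.80 and 0.50. Without tdTomato-positive replicate 1 the number of rises was 0 and that of falls 8, without tdTomato-positive replicate 3 there was 1 rise, and without tdTomato-positive replicate 2 or tdTomato-negative replicate 2 there were 2. With p adjusted over the list alone, 10 fell and 4 rose. The camera adjusted p was 0.0131, and the adjusted p was 0.423 with an estimated correlation.

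Targets of Wnt and beta-catenin rose on balance in tdTomato-positive cells. Of 25 measured, 13 rose, 5 fell and 7 did not pass (median 0.67). Besides Dkk3 and Bmp4, Wif1, a secreted Wnt inhibitor, rose by 3.70 log2 units. Notum, which inactivates Wnt proteins, was 5.52-fold and Lef1, a partner of beta-catenin, at least 2.52-fold higher. Axin2, a widely used Wnt readout, was 1.69-fold higher. Cd44, Myc, Ascl2, Birc5 and Plaur fell, by 1.27, 1.10, 1.02, 0.98 and 0.90. Counts were equal adjusted over the list alone, with 13 and 5, and 10 rose and 4 fell without tdTomato-positive replicate 1 or 2. The camera adjusted p was 0.0290, and the adjusted p was 0.35 with an estimated correlation, 0.112 with median centring and 0.0502 with the strict filter.

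Intestinal stem cell genes went both ways. Of 25 measured, 6 rose, 6 fell and 13 did not pass. Slc14a1 was 8.35-fold and the RNA-binding protein gene Mex3a 2.05-fold higher, and Sox9 and Axin2 rose. Olfm4, which was not detected on the tdTomato-positive arrays, was at least 6.46-fold lower, and Cd44 was 2.41-fold lower. Part of the Olfm4 fold came from tdTomato-negative replicate 1, with 9.16 against 7.15 and 7.22 on replicates 2 and 3. Lgr5, the best known stem cell marker, differed by -0.08 (limma adjusted p = 0.755). There were 8 rises and 6 falls adjusted over the list alone, and 4 and 5 without any 1 of the tdTomato-positive replicates. The median (0.21) and mean (-0.0017) differed in sign, and so did camera's direction with median centring, and the list was not called (camera adjusted p = 0.823).

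Of 34 tuft cell genes on the array, 14 were measured, of which 5 rose, 1 fell and 8 did not pass (median 0.49). With no filter the median over all 34 was 0.02. Vav1, a signalling protein gene also used by immune cells, was at least 4.53-fold, Kctd12 at least 2.22-fold and Ptpn6 1.72-fold higher, and Ltc4s fell by 0.59. Of the tuft genes, 6 rose and 1 fell adjusted over the list alone, and 5 rose and 0 fell without tdTomato-positive replicate 2 or with median centring. The strict filter left 9 tuft genes, of which 2 rose and 0 fell, and 8 enteroendocrine genes, of which 1 rose. The camera adjusted p was 0.0290, and the adjusted p was 0.423 with an estimated correlation, 0.284 with no filter, 0.0660 with the strict filter and 0.0911 without tdTomato-negative replicate 1. Of 18 enteroendocrine genes, Bex2 (2.22-fold), Isl1 (at least 1.26-fold) and Cacna1a (at least 1.56-fold) rose and 15 did not pass, with Chgb at -1.42 (limma adjusted p = 0.298). Without tdTomato-positive replicate 1, 2 rose and 2 fell (median -0.54). When adjusted over the list alone, 2 rose, and with undetected values at the dimmest detected probe Isl1 did not pass. That list was not called (camera adjusted p = 0.793), and its median (0.03) and mean (-0.06) differed in sign. Of 12 secretory progenitor genes, 3 rose (Mxd4, Sox4 and Hes6), 3 fell (Spdef, Gfi1 and Cbfa2t3) and 6 did not pass, as they also counted adjusted over the list alone (camera adjusted p = 0.409). Without tdTomato-positive replicate 1, 1 rose and 2 fell, and without tdTomato-positive replicate 2, 1 rose and 3 fell, as with all probes averaged per gene. The strict filter left 8 genes, with 3 rises and 1 fall.

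Cell cycle genes were lower in tdTomato-positive cells. Of 39 G2 and M phase genes, 24 fell and 15 did not pass (median -0.52), and of 32 S phase genes, 15 fell and 17 did not pass (median -0.45). The mitotic genes Kif23 (1.98-fold), Dlgap5 (1.95-fold) and Cdca8 (1.73-fold) and the DNA synthesis genes Rrm2 (2.39-fold), Cdca7 (1.61-fold) and Blm (difference -0.59) were among them. When adjusted over the list alone, 25 G2 and M phase genes fell and 1 rose, and 19 S phase genes fell. With median centring, 19 G2 and M phase genes fell and 1 rose, and 7 S phase genes fell. Without tdTomato-positive replicate 1, 10 G2 and M phase and 3 S phase genes fell, and without tdTomato-positive replicate 2, 11 and 3. The medians changed less, to -0.51 and -0.37 without replicate 1 and -0.49 and -0.42 without replicate 2. Without tdTomato-negative replicate 2 or 3, 6 and 9 S phase genes fell. Camera of limma gave adjusted p = 4.05e-06 and 3.83e-05, and the adjusted p was 0.423 and 0.488 with an estimated correlation.

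Notch pathway genes showed a few changes. Of 11 Notch targets, Hey1 (2.73-fold), Hes1 (1.67-fold) and Notch1 (1.67-fold) rose, Olfm4 and Myc fell and 6 did not pass, with equal counts adjusted over the list alone and 2 rises and 1 fall without tdTomato-positive replicate 1 or 2 and with either no filter or the strict filter. The list was not called (camera adjusted p = 0.959), and its direction differed between scalings. Of 22 Notch receptors, ligands and cofactors, Dlk1, Maml2 (2.23-fold) and Notch1 rose and 19 did not pass, with 2 rises adjusted over the list alone and 1 without tdTomato-positive replicate 1. Camera did not call it (adjusted p = 0.409), whereas fry, which asks only whether its genes moved one way, gave an adjusted p of 0.000625.

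Of 33 oxidative phosphorylation genes, 7 fell and 26 did not pass (median -0.24), with 3 falling when adjusted over the list alone. Without tdTomato-positive replicate 1 or 2, 1 gene fell, and without tdTomato-positive replicate 3 or tdTomato-negative replicate 2, 3 fell. With median centring 4 fell. Cyc1 was 1.76-fold, Ndufa5 1.58-fold and Uqcrc1 1.51-fold lower (camera adjusted p = 0.00715; adjusted p = 0.35 with an estimated correlation). Of 18 glycolysis genes, Eno2, the neuronal form of enolase, was at least 7.26-fold and Aldoc 1.53-fold higher, Pfkm was 1.64-fold lower and 15 did not pass (camera adjusted p = 0.662). Of 16 hypoxia genes, Vegfa (2.12-fold), P4ha1 (1.59-fold) and Car9 (1.42-fold) rose and 13 did not pass (camera adjusted p = 0.362). The glycolysis and hypoxia counts were equal adjusted over the list alone. Without tdTomato-positive replicate 2 or with the strict filter, 1 glycolysis gene rose, and 2 hypoxia genes rose when any 1 of tdTomato-positive replicates 1 and 3 and tdTomato-negative replicates 1 and 2 was left out.

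Of 22 genes induced by tissue dissociation or as immediate early genes, 10 rose, 1 (Myc) fell and 11 did not pass (median 0.51). Egr2 was 4.20-fold, the heat shock gene Hspb1 2.63-fold and Jun 2.33-fold higher. There were 12 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.00537; adjusted p = 0.579 with an estimated correlation). Without tdTomato-positive replicate 1, 5 rose and 0 fell, and 7 rose when tdTomato-positive replicate 2, tdTomato-positive replicate 3 or tdTomato-negative replicate 2 was left out. Of 20 unfolded protein response genes, 2 rose, 5 fell and 13 did not pass, with Trib3 2.24-fold and Sdf2l1 2.06-fold lower and Atf3 2.08-fold higher (camera adjusted p = 0.528). Rises numbered 3 and falls 5 adjusted over the list alone. With median centring 3 rose and 2 fell, and without tdTomato-positive replicate 1 or 2, 1 rose and 2 fell. Of 20 interferon response genes, Ddx58 rose (1.87-fold), 4 fell, including Oasl1 (2.44-fold) and Tap1 (1.80-fold), and 15 did not pass (camera adjusted p = 0.400). Counts adjusted over the list alone were 1 and 4. The 4 falls became 0 without tdTomato-positive replicate 2 or 3, 1 without tdTomato-positive replicate 1 and 2 without tdTomato-negative replicate 3, and without tdTomato-negative replicate 2 the rise was lost. Median centring gave 1 rise and 2 falls, no background correction 2 and 2, and no filter 0 and 1. Of 11 genes of the NuRD chromatin complex, limma called 0, and 3 passed an unadjusted p of 0.05 (2 higher and 1 lower). None (0) passed adjusted over the list alone, and with median centring or no background correction 1 rose. Chd4, Mta1 and Mbd2 differed by 0.33, -0.60 and 0.52, and camera gave an adjusted p of 0.993, with median (-0.04) and mean (0.03) of opposite sign.

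Some markers of other cell types moved with the groups, but most such markers on the array were not measured. Those measured were 4 of 20 fibroblast and smooth muscle, 8 of 21 endothelial, 5 of 22 immune and 4 of 13 neuron and glia genes. With no filter, the 20 fibroblast and smooth muscle genes showed 1 rise and 1 fall (median 0.04). Of 4 measured fibroblast and smooth muscle genes, Vim, an intermediate filament gene, was 10.2-fold and Fn1 at least 2.04-fold higher in tdTomato-positive cells, and Acta2 differed by 1.02 (limma adjusted p = 0.212). Part of the Vim fold came from tdTomato-negative replicate 1, with a log2 intensity of 9.10 against 10.45 and 10.92 on tdTomato-negative replicates 2 and 3. Of 8 endothelial genes, Sox18 was at least 3.11-fold, Flt1 at least 1.95-fold and Egfl7 1.39-fold higher and 5 did not pass (camera adjusted p = 0.409), with 1 rise left without tdTomato-positive replicate 1 or 2. Of 5 immune cell genes, H2-Ab1 was at least 1.95-fold and Cd74 at least 1.19-fold higher, and Cd14 was 2.11-fold lower (camera adjusted p = 0.667), with 1 rise left without tdTomato-positive or tdTomato-negative replicate 1, or with no filter or no background correction, and Cd74 did not pass with undetected values at the dimmest detected probe. Of 4 neuron and glia genes, Uchl1 was at least 1.64-fold higher, Elavl3 did not pass (limma adjusted p = 0.0511) and neither did Nefm (limma adjusted p = 0.0784). Adjusted over the list alone, the fibroblast list had 2 rises, the endothelial list 3, the immune list 2 rises and 1 fall, and the neuron and glia list 2 rises and 1 fall. The fibroblast and the neuron and glia lists were too short to test. Camera called 11 of 23 lists with the preset correlation, 8 lower and 3 higher, and 0 with an estimated one, where 1 had an unadjusted p under 0.05; fry called 12.

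**Figure D3:**
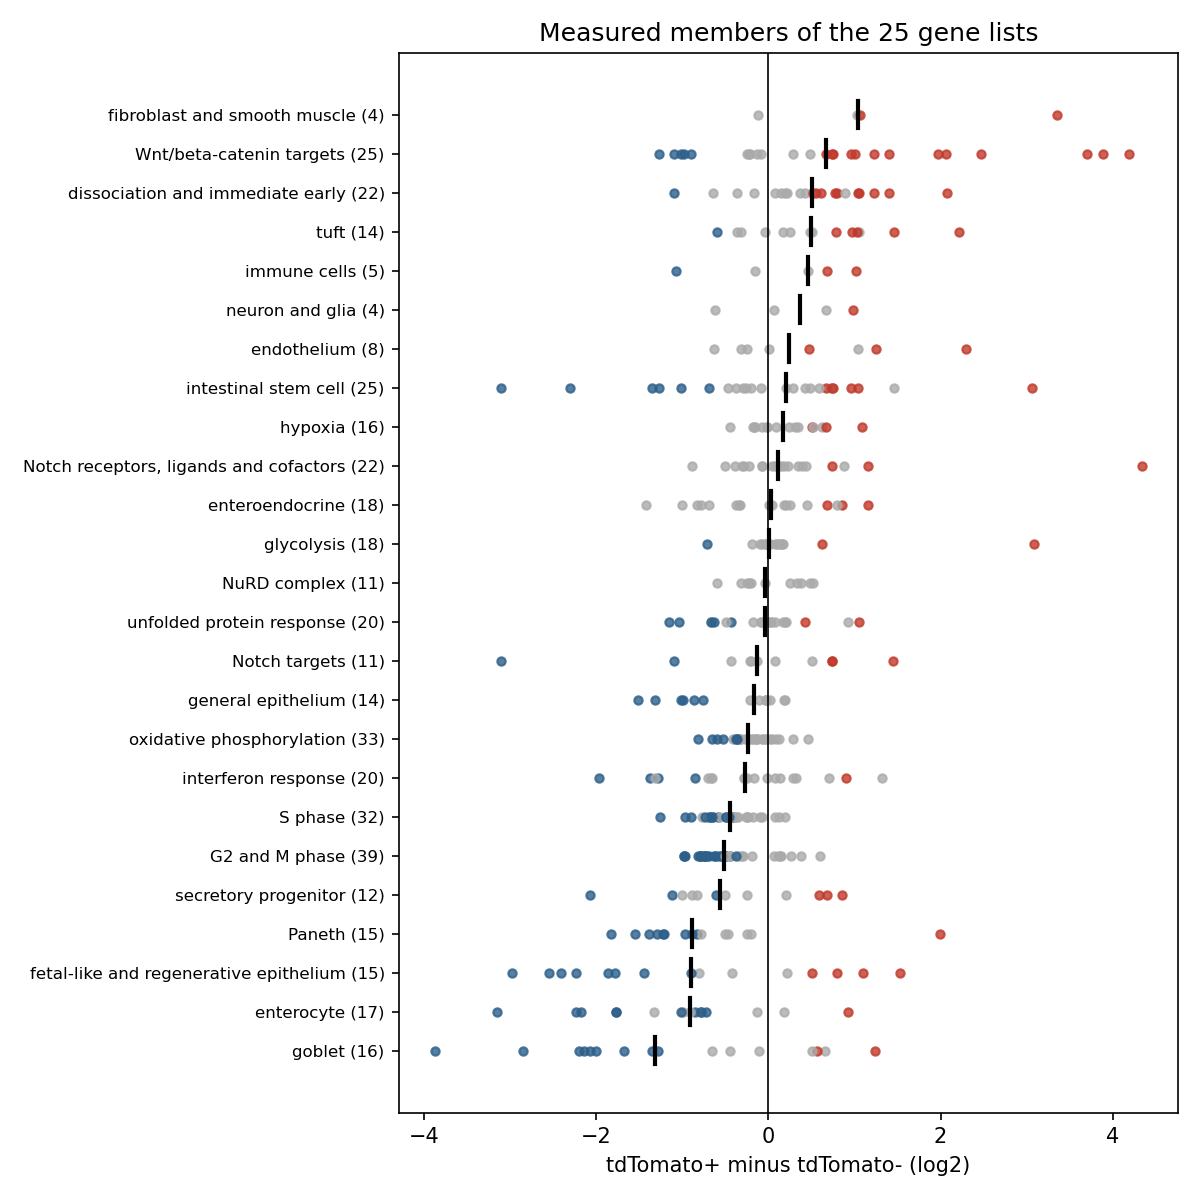
Difference between tdTomato-positive and tdTomato-negative cells (horizontal axis, log2) for each measured member of the 25 lists, 1 list per line with its number of measured genes. Red and blue points passed the limma threshold as higher or lower, gray points did not pass, and black bars are list medians, which ran from -1.32 for goblet genes to 1.04 for the 4 fibroblast and smooth muscle genes.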

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

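The lists mentioned last were made, and their alternatives and the setting of undetected values at the dimmest detected probe chosen, after the data were seen; the other alternatives were planned. The count of changed genes ran from 2715 (a fold of at least 1.5 required) to 5008 (adjusted p under 0.1) over the planned settings that kept all arrays. Leaving out 1 array gave 1926 to 3933 genes, 1094 to 2076 higher and 832 to 1857 lower, with the lowest counts without tdTomato-positive replicate 2 and 2137 without replicate 1, where fewer arrays were fitted. Of the 3718 genes, 3153 were called the same way with median centring and 3405 with the deposited processed values. With the strict filter, 2872 were, and 1 was called the opposite way. Undetected values at the dimmest detected probe gave 3712 genes, 3586 of them called the same way, and ended the calls of Isl1 and Cd74. Prox1 differed by 2.14 to 2.41 over the settings that kept all arrays, with each call kept. The replicate numbers were not shown to pair the samples: deviations of same-numbered samples correlated at 0.073, 0.167 and 0.155 across genes. Every sample correlated best with its own number. The labels give both groups the same replicate numbers but state no pairing, so this is only a hint that the samples were paired. The replicate block gave 3131 genes, with 11 lists called, and among enteroendocrine genes 3 rises and 5 falls, with 8 S phase, 3 oxidative phosphorylation and 5 secretory progenitor genes lower and 5 hypoxia genes higher. No slide block was run, since the columns give no slides.

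Camera called 6 lists with the strict filter and 0 with an estimated correlation. With the estimated correlation the adjusted p was 0.423 for tuft, fetal-like, and G2 and M phase genes, 0.483 for Paneth, 0.488 for S phase, 0.579 for goblet and for immediate early genes, and 0.35 for enterocyte, Wnt target, oxidative phosphorylation and general epithelium genes. With the strict filter it was 0.160 for enterocyte, 0.0502 for Wnt target and 0.0660 for tuft, goblet and general epithelium genes. That filter drops genes that fell out of detection in either group, so it cannot speak against their changes. Median centring gave 0.112 for Wnt targets and no filter 0.284 for tuft genes, which ran from 0.0189 to 0.0911 with 1 array left out. The estimated correlation itself was -0.0149 for Wnt target and 0.00391 for general epithelium genes, below the preset of 0.01. These values argue against a higher correlation between genes as the reason those lists lost their call with the estimate. With the estimate, camera draws its degrees of freedom from the few arrays and not from the genes, which makes it a weaker test. Its smallest unadjusted p over the 23 lists was 0.0421. The simulated list of independently varying, shifted genes went from a camera adjusted p of 3.99e-32 to 0.00928. Calls lost with the estimate therefore say little about whether a list shifted. How much this added to each lost call was not tested. Some lists changed direction with no call in the main or the other setting. These were enteroendocrine (replicate block 0.815; 0.271 to 0.934 with 1 array left out), secretory progenitor (strict filter 0.981), stem cell (median centring 0.936), Notch targets (median centring 0.936, no filter 0.770, replicate block 0.953; 0.793 to 0.985 with 1 array left out) and NuRD (0.825 to 0.994 with 1 array left out). The replicate block changed no call of a list. Of the named genes' values, 17 lost and 7 gained a call over the planned settings, and 38 lost and 3 gained one with an array left out; 0 reversed. The 4 lists made later that camera called kept their calls under each setting except the estimated correlation. Probes near background limit the folds, since the offset and the background setting compress them: the fitted difference of Spock2, undetected in tdTomato-negative samples, was 4.48 with the main setting and 2.46 with no background correction.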

Other observations

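The lists, the single genes and 4 of the tests below were chosen after their values were seen: positive cells mixed into tdTomato-negative samples, normalization between arrays, quantile normalization and the imprinted gene set. The chance splits and the brightness test were set out before their results. After the values were seen, 16 further gene lists were made, so their tests are not independent evidence, and camera called 4 of them. Genes of xenobiotic metabolism, families of detoxifying enzymes, were lower in tdTomato-positive cells: of 75 measured, 36 fell, 7 rose and 32 did not pass (median -0.55, camera adjusted p = 8.48e-05 over the 16 lists; adjusted p = 0.148 with an estimated correlation). Cbr3 fell by 3.35, Cyp2b10 fell by 2.90 and Aldh1a1 fell by 1.90 on the log2 scale, while Cyp2c67 rose by at least 1.96. Secreted Wnt antagonists and feedback inhibitors were higher: of 6 measured, Dkk3, Wif1, Notum, Apcdd1 and Nkd1 rose and Kremen1 differed by 0.04 (camera adjusted p = 0.000588; adjusted p = 0.148 with an estimated correlation). These 5 also belong to the Wnt target list. Of 11 ribosome biogenesis genes, 7 fell, including Bop1 (-0.76) and Rrp9 (-0.75), and 4 did not pass (camera adjusted p = 0.00429; adjusted p = 0.148 with an estimated correlation). Ribosomal protein genes showed 2 falls among 47, with 45 not passing.

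Among 39 homeobox genes, 13 rose and 1 fell, and the list was not called (camera adjusted p = 0.277). Besides Gbx2, Evx1 was 9.59-fold, Dlx3 6.52-fold, Irx5 6.45-fold, Satb1 at least 5.08-fold and Msx1 3.76-fold higher, and Barx2 was 4.63-fold lower. Of 15 collagen genes, 2 fell, Col4a1 (4.08-fold) and Col4a2 (6.31-fold), which encode chains of basement membrane collagen, and 2 rose. The other lists not called were Hox genes, keratins, claudins, MHC genes, BMP signalling, cytokines and chemokines, cholesterol synthesis, solute carriers, collagens and axon guidance. In these, 1 of 11, 3 of 14, 4 of 11, 5 of 18, 1 of 6, 5 of 33, 0 of 11, 33 of 200, 2 of 15 and 7 of 32 genes rose, and 0, 5, 3, 2, 0, 6, 0, 34, 2 and 4 fell. The largest rise among probes detected in both groups was on a probe with no symbol, ILMN_1256343 (difference 4.68), and the largest fall on such a probe was on ILMN_1222219 (-4.12).

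Imprinted genes that act in growth control made up 4 of the 58 genes with a fitted rise of at least 8-fold. Of 15 genes of a network known from mouse studies, 7 were measured, and Dlk1, Peg3 (difference 3.33), Igf2 (3.11) and Cdkn1c (3.06) rose (camera adjusted p = 0.00162; adjusted p = 0.321 with an estimated correlation). The hypothesis that the network rises as a set was tested on the 4 members other than Dlk1, Igf2 and Peg3, which had prompted it. Their median of 0.27 lay at percentile 86.1 of 10000 random lists matched on brightness, and between percentiles 71.8 and 91.5 with each member left out, below the bound of 95 set for it. These 4 include Cdkn1c, whose rise a median of so few genes does not show, so the percentile does not decide the question. Igf2r and Gnas differed by 0.38 (SE 0.15) and 0.16 (SE 0.16) and did not pass, and neither did Grb10, detected on 2 of 3 tdTomato-positive arrays. With its undetected value at the dimmest detected probe the median was also 0.27. The values of Igf2r and Gnas argue against a rise of the whole measured set by an amount like that of Dlk1, Peg3, Igf2 and Cdkn1c. A smaller rise of the other 3 was not excluded.

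The lower S phase and G2 and M phase genes were weighed against technical explanations. Of 71 genes in either list, 39 fell (median -0.49), and of 10000 random lists matched on brightness 0% had a median as low, the lowest being -0.26, which argues against a brightness-dependent bias of the arrays. With median centring the median was -0.38, and -0.49 relative to all genes, so quantile normalization does not account for the whole fall, although 7 S phase genes fell in place of 15. The number of genes called depended on single arrays, with 3 S phase genes lower without tdTomato-positive replicate 1 or 2. The S phase median was -0.37 and -0.42 in these fits, and the calls over all genes fell too, to 2137 and 1926. What stays open is the correlation between cell cycle genes, estimated at 0.338 for S phase and 0.246 for G2 and M phase genes. With the estimate both lists lost their call, but so did lists whose estimate lay below the preset. The estimated setting is a weaker test for any list, so the lost calls do not show that correlation accounts for the fall. The handling of cells before and during the sort also stays open. It was not measured, and whether the higher immediate early genes came from it was not tested.

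The other pattern was that tdTomato-negative replicate 1 stood apart, with the lowest Prox1. Under 4 scalings, at least 11.2 times as many genes differed 2-fold between it and either other replicate as between those 2 (558 and 580 against 50 with the main scaling), which argues against background correction or normalization between arrays. If tdTomato-positive cells mixed into the other replicates were the cause, Prox1 would imply a share of 22.8% in replicate 2 and 23.5% in replicate 3. Of 108 other genes at least 8-fold brighter in tdTomato-positive arrays than in replicate 1, only 23.1% and 34.26% implied a share within 2-fold of that, with medians of 5.66% and 6.35% (quartiles 2% to 14.9% and 2.52% to 17.8%), which argues against mixing as the whole cause. The labels give no group that sets the replicates apart, so no biological explanation was tested.

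The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3718 genes and the highest other split 0, where at most 383 genes had an unadjusted p under 0.05 in limma; 1 of the 10 splits gave as many genes. For lists, 1 of the 10 splits gave as many as the real 11, and the highest other split gave 9. Each of the 9 other splits still sets 2 arrays of a group and 1 of the other against the reverse, so part of the group difference stays in it and its calls are no measure of chance.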
